A study of Mus musculus with 10 samples.

How the data were processed

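Per the labels, RNA was sequenced from epididymal white adipose tissue, the visceral fat pad beside the testis, of male C57BL/6 mice. The 10 samples fall into 4 groups. Adenovirus carrying GFP (3 samples) or IGF2 (2 samples) was injected into the fat of obese mice 2 times a week for 4 weeks, and a lentivirus carrying a control (3 samples) or IGF2-directed (2 samples) short hairpin RNA was given to mice aged 3 to 4 weeks. Per the labels, sequencing was done by a commercial service, with genes selected by a log2 fold change over 1 in size and an unadjusted p under 0.05. The aligner, the counter and the genome build are not given in the sources used here.

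The deposited data analysed here are a single table of 28 columns that holds 4 comparisons side by side, 7 columns each, with no name for any of them. Per the file headers, each comparison gives an identifier with its gene symbol, a base mean, a log2 fold change, its standard error, a test statistic, a p-value and an adjusted p. The base mean is a normalised read count averaged over the libraries of the comparison, as the authors deposited it. The log2 fold changes and their standard errors are the authors' deposited values. The test statistic is a deposited score that equals the fold change divided by its standard error to within 1.3e-07 in every listed row. The p-values and adjusted p-values are also the authors', per the file headers, and rows with an empty adjusted p were kept as untested. No column holds values of a named sample: 0 of the 24 value columns could be tied to any of the 10 samples.

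All 35395 identifiers in the table are human gene identifiers, and 0 of them are among the 55450 identifiers of the mouse annotation. For this reason no comparison was assigned to a group of mice. The tests fixed before the data were examined, edgeR fits of counts per sample, could not be run, and no fold change, error or p-value was estimated per group. The deposited statistics are described in their place. Positive fold changes are called higher in the numerator and negative ones lower, and the comparisons are called the first to the fourth in the order in which they stand.

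The number of libraries behind each comparison was read from rows with few reads. A row's base mean is a sum of whole reads, each worth a fixed step per library. Sets of 1 to 4 steps, 1 of them fixed by the lowest row, were searched for the set that gave the most low rows within 2e-06. For 5 steps, 1 more step was only added to the best 4. The smallest number of steps that gave all low rows was taken. The side of each library came from the sign of the fold change in rows with reads in that library alone. Means of the libraries on each side were then derived from the base mean and the fold change, with 2 libraries a side, and compared between comparisons over 9552 genes with a base mean of at least 10 CPM in every comparison. CPM here is the base mean scaled to the sum of base means of its comparison. Sides whose log2 means differed with an SD under 0.01 were taken as the same set of libraries. Reads of a library were approximated as its size factor times the summed means of its side. In simulated tables with known steps, 4 of 4 size factors were recovered within 0.001 in each comparison.

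Genes were called at a deposited adjusted p under 0.05, and the selection stated in the labels was counted beside it. The rule for named genes was fixed before the data were examined: the 10 largest rises and the 10 largest falls among called genes with a base mean of at least 2 CPM, and the 4 members of each gene list with the smallest p. Its condition that libraries of the groups do not overlap could not be applied, a change made after the table had been seen, and genes named after clones were left out. Genes of sex chromosomes used to tell sex were left out as well. The text gives only part of the list members that the rule takes, and an item among those left out is not reported here. A fold against a set below the value of 1 read is given as a lower bound against a floor of 3 reads over the set's 2 libraries. No fold is given where the lower set lay between that value and the floor.

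The 27 gene lists were fixed before the data were examined as mouse genes and were read here under human symbols, 28 of which were written by hand after the table had been seen. Another 7 lists were added after the largest changes had been seen. Lists with at least 5 tested members were tested with the pre-ranked form of camera (limma 3.58.1, R 4.3.3) on the deposited statistics of genes with an adjusted p, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the fixed or over the added lists of a comparison. A correlation could not be estimated without values per library, so a preset correlation of 0.05 was the alternative. The median of each list was also ranked among those of 10000 random lists of tested genes matched on base mean. In 100 simulated runs on the 22550 genes of the third comparison, a lowered list was called in 100 runs and 0.2% of the other lists were called. These statistics were drawn independently for each gene. The runs therefore check the procedure and cannot show how often correlated genes would lead to false calls. In simulated statistics with 200 genes changed 4-fold, calls took in 89% of these among 13009 genes in the first comparison, 86% of 13075 in the second, 94.5% of 13512 in the third and 94.5% of 13599 in the fourth. Unchanged genes made up 4.3%, 5.0%, 3.1% and 5.5% of the calls. Here too genes were drawn independently, and the deposited standard errors were taken as exact. These shares check the adjustment for many genes and do not measure the power of 2 libraries a side. Correlations of fold changes between comparisons were computed over genes of at least 2 CPM in both and set beside values simulated from the deposited standard errors with no effect, in which both sides contributed equally to each variance or the shared side gave 25%, 75% or 100% of it.

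Alternatives were another adjustment, another threshold, a minimum base mean, fold changes centred on the median gene, other genes or ranks in the list test, a higher minimum for correlations, and other parts of the variance in simulated correlations. All of them were chosen after seeing the data. Analyses were run in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.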

Results

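RNA sequencing was described for epididymal fat of mice in which IGF2, a fetal growth factor, was raised with an adenovirus or lowered with a lentiviral hairpin. The labels list 3 Ad-GFP, 2 Ad-IGF2, 3 NC-RNAi and 2 IGF2-RNAi samples, and the design asks how gene expression in fat differs between Ad-IGF2 and Ad-GFP and between IGF2-RNAi and NC-RNAi. The authors' deposited table does not carry these comparisons in a form that could be tied to the groups, because its 35395 identifiers are human and its 4 comparisons are unnamed. No effect of IGF2 in mouse fat is therefore reported. What follows describes the 4 comparisons as they stand, and every fold change, standard error and p-value is the authors' own unless a test is named.

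The base means in the authors' deposited table fitted 2 libraries on each side of every comparison. Steps for 4 libraries gave 100% of the 3258, 3125, 4110 and 4629 low rows of the first to the fourth comparison, and steps for 3 libraries gave 75.5%, 73.0%, 72.0% and 71.7%. Steps for 5 libraries also gave 100% in every comparison, as they must once 4 do, so the smallest number was taken. In simulated tables of 5 libraries, 4 steps gave 71.5% to 73.5% of such rows where the last library had a size factor of 1.2 and 83.9% to 86.0% where it had 0.6, but 100% at 0.3, so that another library of so low a depth would be missed. Steps for 5 libraries gave 100% at 1.2 but only 88.4% to 91.0% at 0.6, so the search did not always find the true 5 steps. The derived side means in the authors' deposited table also showed which libraries recurred. The first and the third comparison had the same reference set, the second and the fourth shared another, the first and the second had the same numerator set, and the third and the fourth shared a different numerator set. Log2 means of these 4 matched pairs differed with an SD of 0.0006 to 0.0019 over 9552 genes, against 0.343 to 0.773 for the 24 other pairs of sides. With 2 numerator and 3 reference libraries assumed, the SD of the matched pairs was 0.038 to 0.060, and with 3 and 2 it was 0.039 to 0.061. The table thus rested on 8 libraries in 4 sets, where the labels describe groups of 2 and 3. Base means in the authors' deposited table summed to 20065481, 18602212, 15882592 and 14705083 in the first to the fourth comparison, which is the mean normalised depth of a library.

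IGF2, the gene changed in the described mice, and genes that mark fat tissue had hardly any reads. IGF2 had 2 reads over the reference set and 0 over the numerator set in the first and the third comparison of the authors' deposited table, and no row in the others. Neither count allows a fold to be given. As the first and the third comparison have the same reference set, the 2 reads of IGF2 are the same reads in both. ADIPOQ, which encodes the fat hormone adiponectin, had 1 read on each side of the first comparison, 3 numerator reads against 1 in the third and 3 against 0 in the fourth, as derived from the authors' deposited table. The base means of ADIPOQ, CFD and PLIN1 in the first comparison of the authors' deposited table came to 0.0308, 0.0312 and 0.0542 CPM of the summed base means.

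In the third and the fourth comparison, which share their numerator set, stress genes rose and cell division genes fell. HSPA6, an inducible cytosolic heat shock protein (ENSG00000173110), was 1076-fold higher in the third comparison of the authors' deposited table (log2 fold change 10.07, SE 0.81) and 1195-fold higher in the fourth (10.22, SE 0.52). All 20 tested genes of the endoplasmic reticulum stress list rose in the third comparison of the authors' deposited table, and 19 of 20 rose in the fourth, with median log2 fold changes of 1.45 and 1.59. Cell cycle genes fell in 23 of 24 and 24 of 24 cases, with medians of -1.74 and -1.85 in the authors' deposited table.

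Among the stress genes, HERPUD1, a factor of protein disposal at the endoplasmic reticulum, had log2 fold changes of 4.14 (SE 0.15) and 3.87 (SE 0.17) in the third and the fourth comparison of the authors' deposited table. DNAJB9, a chaperone cofactor of that compartment, had 3.92 (SE 0.18) and 3.66 (SE 0.20), and CHAC1, a glutathione-degrading enzyme, had 4.10 (SE 0.23) and 5.05 (SE 0.28) in the authors' deposited table. DDIT3, a stress-induced transcription factor also known as CHOP, had 3.67 (SE 0.21) and 3.49 (SE 0.25) in the authors' deposited table. The list test gave an adjusted p of 5.06e-48 in the third and 8.85e-33 in the fourth comparison (camera). The counts adjusted over the list alone were 20 and 19.

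In the list of immediate early and heat shock genes, 13 of 20 tested genes rose and 1 fell in the third comparison of the authors' deposited table, and 14 rose and 1 fell in the fourth. HSPA1B had log2 fold changes of 5.28 (SE 0.21) and 5.73 (SE 0.20) in the authors' deposited table, and it shares nearly its whole sequence with HSPA1A, so that the split of reads between them is uncertain. DNAJB1, a cochaperone, had 2.88 (SE 0.16) and 2.74 (SE 0.19), and FOSB, an immediate early transcription factor, had 4.45 (SE 0.35) in the third comparison of the authors' deposited table. The list was called higher with an adjusted p of 3.05e-16 and 2.10e-24 (camera), and the counts adjusted over the list alone were 14 and 16.

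The fall of the cell cycle list had an adjusted p of 1.24e-28 in the third and 9.25e-43 in the fourth comparison (camera), and 23 and 24 genes were called when adjusted over the list alone. MKI67, a marker of dividing cells, had a log2 fold change of -2.19 (SE 0.17) in the third comparison of the authors' deposited table, and TOP2A, a topoisomerase of dividing cells, had -1.92 (SE 0.16). In the fourth comparison of the authors' deposited table the mitotic genes CCNB1, PLK1 and KIF20A had -3.21 (SE 0.19), -2.46 (SE 0.18) and -3.04 (SE 0.22).

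**Figure D1:**
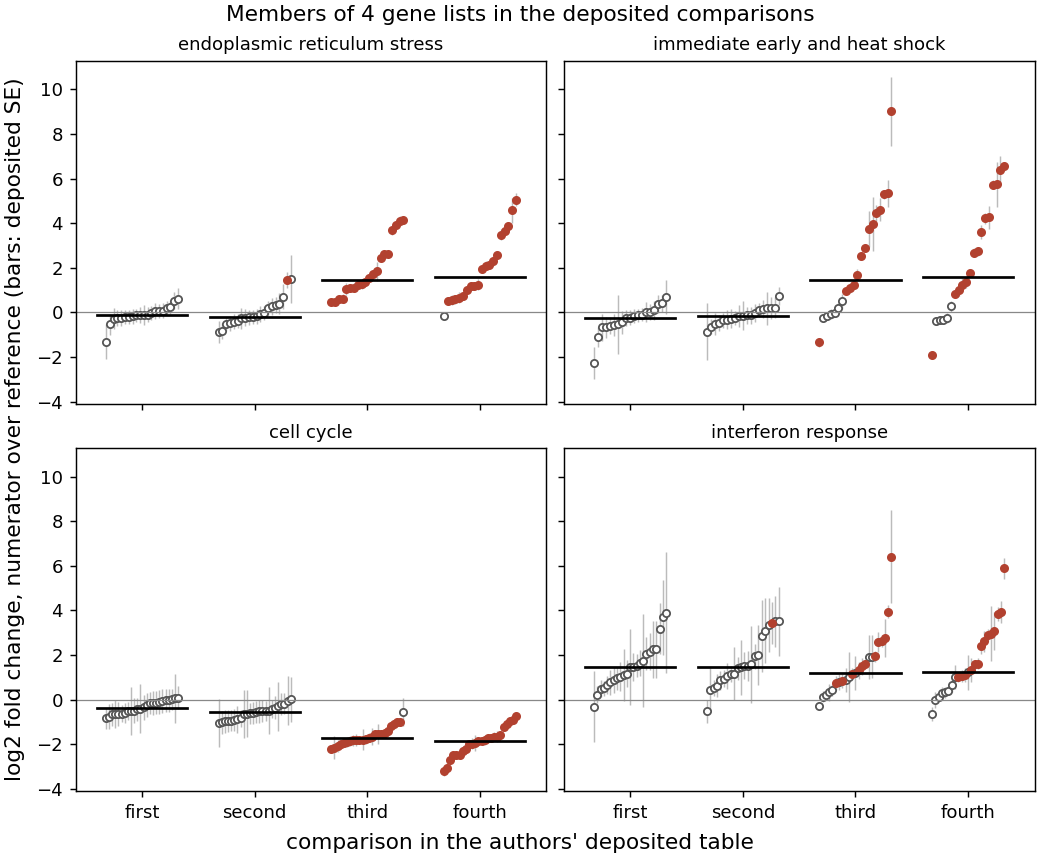
Log2 fold changes (vertical axis, numerator over reference) of the tested members of 4 gene lists in each comparison of the authors' deposited table; each point is a gene with its deposited SE, filled points have an adjusted p under 0.05 and black lines are medians. Median values for endoplasmic reticulum stress genes were -0.12 and -0.18 in the first and the second comparison and 1.45 and 1.59 in the third and the fourth.

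Genes of the interferon response list rose in 12 of 23 cases in the third and 14 of 23 in the fourth comparison of the authors' deposited table, and none fell. IFIT2, an interferon-induced RNA-binding protein, had log2 fold changes of 3.93 (SE 0.29) and 3.84 (SE 0.31), and IFIH1, a sensor of double-stranded RNA, had 2.63 (SE 0.26) and 2.90 (SE 0.28) in the authors' deposited table. The list test gave adjusted p values of 7.52e-07 and 6.07e-09 (camera), with 12 and 14 genes called when adjusted over the list alone. Inflammatory mediators rose in 10 of 15 cases in both comparisons of the authors' deposited table, with 1 fall in the third and 2 in the fourth (adjusted p 2.02e-06 and 5.94e-05, camera; 11 and 13 genes adjusted over the list alone). ICAM1, an adhesion molecule, had log2 fold changes of 4.70 (SE 0.54) and 4.52 (SE 0.55), and the chemokine CCL5 had 5.27 (SE 0.51) and 2.88 (SE 0.39) in the authors' deposited table.

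Genes of mitochondrial respiration fell in 13 of 27 cases in the third and 17 of 27 in the fourth comparison of the authors' deposited table, with medians of -0.47 and -0.68 and no rise (adjusted p 0.000113 and 2.63e-07, camera; 14 and 21 genes adjusted over the list alone). NDUFV1, a subunit of complex I, had log2 fold changes of -1.47 (SE 0.19) and -1.66 (SE 0.23) in the authors' deposited table. Of 24 tested genes of fatty acid and triglyceride synthesis, 11 fell and 1 rose in the third comparison and 10 fell and 2 rose in the fourth comparison of the authors' deposited table (adjusted p 0.00926 and 0.0228, camera; 12 and 12 adjusted over the list alone). The smallest p values in that list in the third comparison included those of TKT and GPAT3, and in the fourth that of PGD, with log2 fold changes of -1.21 (SE 0.17), -1.41 (SE 0.19) and -1.60 (SE 0.20) in the authors' deposited table. With a preset correlation of 0.05 the adjusted p of this list was 0.0558 and 0.0901, and among genes of at least 2 CPM it was 0.0875 and 0.118. Its medians stood at the percentiles 7.90 and 10.9 of random lists matched on base mean, where well expressed genes lay lower in general, and those of the respiration list stood at 3.72 and 0.36. In the third comparison the extracellular matrix list was called lower (adjusted p 0.00168, camera), with 9 falls and 4 rises among 26 genes of the authors' deposited table. This call was lost on ranks (adjusted p 0.237), its median stood at the percentile 53.95 of matched lists, and in the fourth comparison the list was not called (adjusted p 0.256, camera), with a median of 0.11 in the authors' deposited table. Its median of -0.14 in the third comparison became 0.02 when centred on the median gene. THBS1, the matrix protein thrombospondin, had a log2 fold change of -2.95 (SE 0.14) in the third comparison of the authors' deposited table.

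Markers of other cell types were also called higher in these comparisons. Macrophage markers rose in 10 of 17 cases in the third and 9 of 16 in the fourth comparison of the authors' deposited table, at median base means of 27.3 and 32.8. Their median log2 fold changes were 3.07 and 2.34 in the authors' deposited table and 1.86 and 1.85 with genes at the floor set to their bound. Called members with more reads in the third comparison included CTSS of the macrophage list and IL2RB of the T and NK cell list. HPX of the liver list, ATP2A1 of the muscle list, and CD55 and F3 of the progenitor list were others. In this order their base means were 114, 143, 133, 242, 921 and 2475 in the authors' deposited table. The lists of T and NK cells, adipose progenitors, skeletal muscle and liver were called in both comparisons as well, with 3, 3, 2 and 3 called genes in the third comparison of the authors' deposited table. With a preset correlation of 0.05 their adjusted p was 0.0672, 0.0505, 0.0558 and 0.0558 in the third comparison and 0.0858, 0.0858, 0.0831 and 0.0484 in the fourth. Among genes of at least 2 CPM the macrophage and progenitor lists stayed called, with an adjusted p of 0.00162 and 0.0132 in the third and 0.000305 and 0.0116 in the fourth comparison, and the others had too few members. On ranks the progenitor list was not called in the fourth comparison (adjusted p 0.0573), and over all listed genes the T and NK list was not called in the third (adjusted p 0.0692). Against matched random lists the medians stood at the percentiles 99.99 and 99.96 for macrophages, 92.25 and 96.67 for T and NK cells, 98.76 and 91.74 for progenitors, 97.15 and 99.61 for muscle, and 91.17 and 99.66 for liver. PTPRC, a surface protein of white blood cells in general and chosen after the table had been seen, had 1 numerator read and 2 reference reads in both comparisons, as derived from the authors' deposited table. Weakly expressed genes in general lay higher in these comparisons, as the plot of expression classes shows.

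Beside HSPA6, the rises taken by the rule for named genes were against sets with hardly any reads. In the third comparison of the authors' deposited table IGHE, BMP7, EGR2, ERG, GABRR2, NLRP5 and MCF2L were at least 103-fold, 101-fold, 56-fold, 54-fold, 50-fold, 48-fold and 45-fold higher. In the fourth comparison of the authors' deposited table the bounds were 94-fold for IGHE, 93-fold for BMP7, 88-fold for FUT1, 84-fold for SLC6A18 and 58-fold for SPRR2D. HSPA7, a near copy of HSPA6 whose reads are uncertain, had derived means of 416 and 0.88 normalised reads in the third and 382 and 0.49 in the fourth comparison of the authors' deposited table. CRYM had derived means of 146 and 0.44 in the third comparison, and KLHDC7B, RBBP8NL and OLR1 had numerator means of 336, 274 and 242 against 0.49 in the fourth comparison of the authors' deposited table. A rise against a set with many reads was that of HSPA1A in the fourth comparison, 93.8-fold from a reference mean of 439 in the authors' deposited table (log2 fold change 6.55, SE 0.19), with the same doubt about reads shared with HSPA1B. The falls in the third comparison were smaller, from 8.9-fold for FAM20C, a secretory pathway kinase (log2 fold change -3.16, SE 0.16), to 5.9-fold for ZNF488 in the authors' deposited table. Between them stood MAP2K6, KIT, PDE4B, THBS1, ASB9, PDE7B, PLXNA4 and WNT7B. In the fourth comparison of the authors' deposited table ANKRD30A fell 88.1-fold (log2 fold change -6.46, SE 0.93), ADAMTS15 27.6-fold, NUDT4B 23.4-fold and SHISA2 21.2-fold, and PDPN, a mucin-type membrane protein, had a log2 fold change of -4.39 (SE 0.28). The derived numerator means of ANKRD30A and NUDT4B were only 1.54 and 3.11 normalised reads, so their folds are imprecise. ANO4, IQSEC1, L1CAM, SH3RF3 and FBLN1 fell between 13.2-fold and 9.8-fold in the authors' deposited table. Of these falls, ANKRD30A, ADAMTS15, SHISA2, ANO4, SH3RF3 and FBLN1 were also among the named falls of the second comparison. It has the same reference set and the other numerator set. None of them was among the named falls of the third comparison, which shares its numerator set with the fourth. Those named falls are only the 10 largest, so smaller falls of these genes there are possible. The second and the fourth comparison also use the same reference libraries. Whether these falls go with the reference set or with the numerator set was not tested.

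In all, 6971 genes were called in the third and 7685 in the fourth comparison of the authors' deposited table. Of these, 3340 and 3810 were higher and 3631 and 3875 lower. The median gene of at least 2 CPM lay at -0.16 and -0.15 on the log2 scale of the authors' deposited table, and centring on it gave 4074 higher and 2564 lower genes in the third and 4483 higher and 2988 lower in the fourth comparison. Adjustment over genes of at least 2 CPM went the other way, with 2406 higher and 3831 lower genes in the third and 2730 and 3944 in the fourth. A log2 fold change over 1 in size left 2438 higher and 1146 lower genes in the third and 2839 and 1764 in the fourth. The share of called genes that were higher thus ran from 38.6% to 68.0% in the third and from 40.9% to 61.7% in the fourth comparison over the settings tried. The selection stated in the labels took 4443 and 5430 genes of the authors' deposited table, and 2634 and 3438 of at least 2 CPM.

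**Figure D2:**
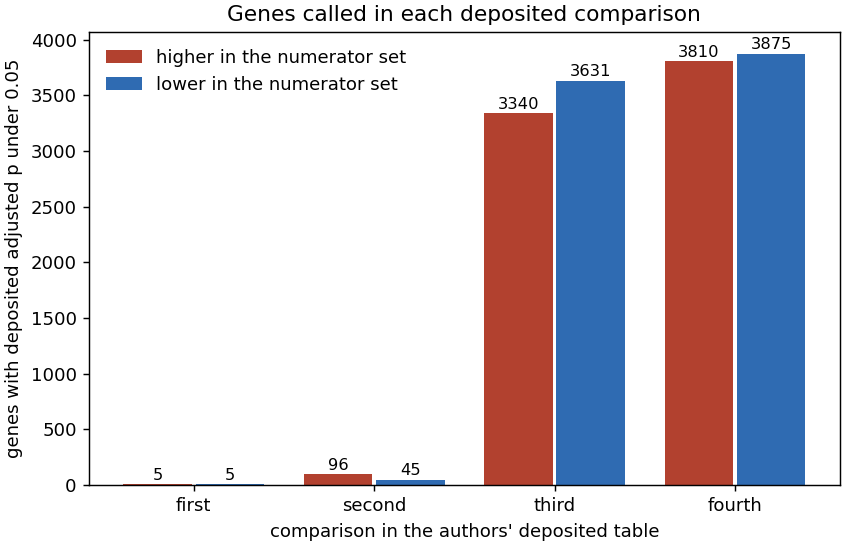
Number of genes with a deposited adjusted p under 0.05 (vertical axis) in each comparison of the authors' deposited table, split into those higher and those lower in the numerator set. The first comparison has 5 and 5 genes, the second 96 and 45, the third 3340 and 3631, and the fourth 3810 and 3875.

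The first comparison held 10 called genes in the authors' deposited table. ARHGDIB was 6.82-fold higher (log2 fold change 2.77, SE 0.52), followed in the authors' deposited table by the lipase LIPG (6.04-fold), HIST1H2AC (5.44-fold), NXN (4.58-fold) and CD70, a ligand of the tumour necrosis factor family (4.53-fold). SERPINB2, an inhibitor of plasminogen activators, was 4.26-fold lower, SCG5 2.99-fold lower and ALDH1A3, an enzyme of retinoic acid synthesis, 2.76-fold lower in the authors' deposited table. HNRNPA1P10 and RPL9P7, 5.40-fold and 3.39-fold lower in the authors' deposited table, are processed copies of expressed genes and are uncertain. Centring on the median gene gave 8 higher and 4 lower genes in place of 5 and 5. The selection stated in the labels, on unadjusted p, took 443 genes of the authors' deposited table, 406 higher and 37 lower.

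Gene lists moved in the first comparison although few single genes passed. Interferon response genes had a median log2 fold change of 1.47 in the authors' deposited table with 0 of 23 genes called, or 5 adjusted over the list alone (adjusted p 2.88e-15, camera). Cholesterol synthesis genes had a median of 0.63 with 0 of 23 called, or 6 adjusted over the list alone, in the authors' deposited table (adjusted p 5.70e-11, camera). Their smallest p values belonged to MSMO1, with a log2 fold change of 1.51 (SE 0.44), and to HMGCS1, with 0.98 (SE 0.35), in the authors' deposited table. In the second comparison, which has the same numerator set, this list had a median of 0.10 in the authors' deposited table. It was not called there (adjusted p 0.785, camera), and 0 genes were called when adjusted over the list alone. In the third comparison, with the reference set of the first, its median was 0.19, with 7 of 24 genes higher and 2 lower. It was not called there (adjusted p 0.0762, camera) except among genes of at least 2 CPM (adjusted p 0.0375). In the fourth its median was -0.22, with 3 of 23 genes higher and 7 lower. Part of the rise in the first comparison may thus go with the reference set. In the first comparison the cell cycle list was lower, at a median of -0.38 in the authors' deposited table (adjusted p 0.00161, camera). The immediate early and heat shock list was lower as well, at -0.23 in the authors' deposited table (adjusted p 0.00650, camera). With a preset correlation of 0.05 the latter had an adjusted p of 0.0562.

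The second comparison, which shares its numerator set with the first, held 141 called genes in the authors' deposited table, 96 higher and 45 lower. SH3PXD2B, RHOU, IFI27 and S1PR3 were 32.2-fold, 30.0-fold, 26.8-fold and 26.7-fold higher in the authors' deposited table. IFI27 is an interferon-induced gene and S1PR3 a receptor for sphingosine 1-phosphate. DNAH6, a dynein heavy chain, was 12.5-fold higher with a log2 fold change of 3.64 (SE 0.36), and CCND2, a cyclin, was 14.9-fold higher in the authors' deposited table. ZNF208, SULF2, CELF2-AS1 and LINC00310 were between 19.2-fold and 11.6-fold higher in the authors' deposited table, and reads of the antisense gene CELF2-AS1 are uncertain. ANKRD30A was at least 108-fold lower, SH3RF3 35.2-fold, SHISA2 27.8-fold (log2 fold change -4.80, SE 0.39) and OVAAL 24.8-fold lower in the authors' deposited table. SH3RF3 and OVAAL had derived numerator means of only 2.75 and 4.12 normalised reads (SE 0.81 and 0.78), so their folds are imprecise. The matrix genes ADAMTS15, FBLN1, MMP1 and FBLN2, together with ANO4 and the receptor TNFRSF1B, were between 11.2-fold and 8.7-fold lower in the authors' deposited table. The selection stated in the labels took 1012 genes of this comparison, 730 higher and 282 lower.

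Interferon response genes had a median of 1.48 in the second comparison of the authors' deposited table, with RSAD2 called among 22 genes (log2 fold change 3.42, SE 0.94) and 8 genes adjusted over the list alone (adjusted p 1.01e-09, camera). The cell cycle list had a median of -0.56 with 0 of 24 genes called in the authors' deposited table (adjusted p 0.000262, camera). The respiratory chain list, at -0.30, and the list of IGF and insulin signalling, at 0.28 in the authors' deposited table, were called with adjusted p values of 0.00986 and 0.0190 (camera). Both calls were lost with a preset correlation of 0.05, at an adjusted p of 0.119 and 0.159, and the latter also among genes of at least 2 CPM (adjusted p 0.0721).

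Fold changes of the third and the fourth comparison in the authors' deposited table correlated across 13358 genes at r = 0.90, where the shared numerator set alone gave r = 0.47 in simulated data with no effect. Their covariance was 1.16 against a simulated 0.0493. They had 2671 genes higher in both and 2599 lower in both in the authors' deposited table, where independent lists would share 587 and 646, and part of this excess may come from the shared libraries. The second and the fourth comparison, with a common reference set, correlated at r = 0.56 against a simulated 0.47, with covariances of 0.291 and 0.0578, and shared 64 higher and 38 lower genes of the authors' deposited table against 15.2 and 10.1, where the shared libraries may add to the excess as well. The first and the second comparison, with a common numerator set, correlated at r = 0.60 against a simulated 0.50, with covariances of 0.169 and 0.0931, in the authors' deposited table. The first and the third, with a common reference set, correlated at r = 0.35 in the authors' deposited table, below the simulated 0.49, although their covariance of 0.117 was above the simulated 0.0609. These simulated values take equal variance from both sides, which may not hold. With 25% or 75% of the variance from the shared side they were 0.23 and 0.75 for the first and the second, 0.25 and 0.73 for the first and the third, 0.25 and 0.72 for the second and the fourth, and 0.23 and 0.72 for the third and the fourth comparison. Of these pairs, only the third and the fourth comparison correlated outside that range, and with all of the variance from the shared side their simulated value was 0.97. The covariances of all 4 pairs were above those simulated with 75%, which were 0.143, 0.0887, 0.0925 and 0.0703 in the same order. With all of the variance from the shared side the simulated covariances were 0.188, 0.117, 0.120 and 0.0975. The first pair lay below this, the next was about equal to it, and the second and the fourth comparison and the third and the fourth lay above it. The first and the fourth comparison, with no set in common, correlated at r = 0.16 and the second and the third at r = 0.20 in the authors' deposited table, against simulated values of -0.01 and -0.01. Genes are not independent replicates, and no p-value is attached to these 6 correlations across genes.

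**Figure D3:**
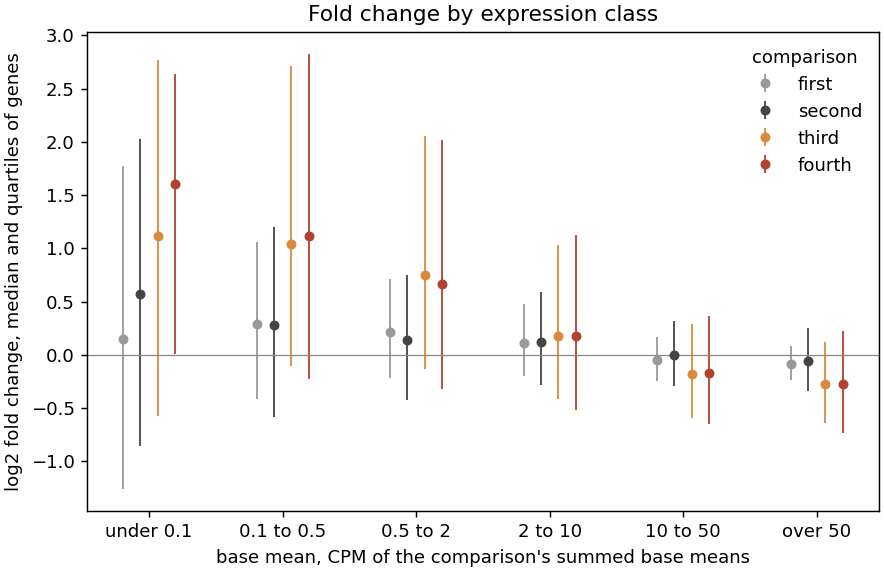
Median log2 fold change (vertical axis, bars give the quartiles of genes) by class of base mean in CPM of the summed base means (horizontal axis) in the 4 comparisons of the authors' deposited table. In the third and the fourth comparison the medians run from 1.12 and 1.60 in the lowest class to -0.27 and -0.28 in the highest.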

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

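All alternatives here were chosen after seeing the data. No paired analysis was possible because the table holds no values per sample. For the same reason the alternatives fixed before the data were examined (another count tool, another normalization, a filter on low counts, other samples in the fit, each replicate left out, an estimated correlation) were not run. Of 95 values recomputed under an alternative, 69 were within tolerance: counts within 1.5 times, list medians of the same sign, correlations within the 95% interval. That interval treats genes as independent, which they are not. Many of the values are list medians centred on a median gene that lay at -0.16 at the furthest. Only the extracellular matrix median in the third comparison was smaller in size than that shift, so the others could not change sign. The rest include the simulated correlations with other parts of the variance, which depend on the part by construction. The count of 69 is therefore no measure of robustness. Adjusting over every listed gene left 6 genes called in the first comparison in place of 10, since more genes entered the adjustment. An adjusted p under 0.1 gave 241 genes in the second comparison. Requiring a log2 fold change over 1 gave 3584 genes in the third and 4603 in the fourth. Among genes of at least 2 CPM, the selection stated in the labels took 286, 2634 and 3438 genes in the first, the third and the fourth comparison, because fewer genes entered. A preset correlation of 0.05 left 2 lists called in the second comparison and 8 in the third. In the fourth, 8 of 12 stayed with that correlation and 8 at 2 CPM or more, at the edge of the tolerance. The median of the extracellular matrix list in the third comparison went from -0.14 to 0.018 when centred on the median gene. At 10 CPM or more, correlations were 0.31 for the first and the third comparison, 0.14 for the first and the fourth, 0.17 for the second and the third and 0.88 for the third and the fourth, and the cause was not tested. Depth limits rows of few reads, where fold changes rest on the fitted values of single reads.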

Other observations

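All tests and lists in this part were chosen after the results had been seen. In the third and the fourth comparison of the authors' deposited table, 17 of 20 genes of an added list of cytosolic chaperones rose and 1 fell, with medians of 1.57 and 1.60 (adjusted p 1.78e-31 and 2.20e-31, camera). This list shares members with the heat shock list. Autophagy receptors and machinery rose in 9 of 13 and 7 of 13 cases with 1 fall in each, led by MAP1LC3B at 2.68 and 2.19 and by SQSTM1, a receptor for ubiquitinated cargo, at 1.88 and 1.78 in the authors' deposited table (adjusted p 4.89e-08 and 0.000152, camera). Targets of p53 rose in 12 of 14 cases in the third comparison and in 6 of 14 with 1 fall in the fourth, and GDF15, a stress-induced hormone, had log2 fold changes of 2.84 and 1.77 in the authors' deposited table (adjusted p 2.21e-10 and 0.00804, camera). Targets of NRF2, the regulator of the oxidative stress response, had 5 rises and 1 fall in the third and 6 rises and 3 falls in the fourth comparison, with HMOX1 at 3.60 and 4.15 in the authors' deposited table (adjusted p 0.00325 and 1.12e-05, camera), and the first of these calls was lost on ranks (adjusted p 0.0783). Ribosomal protein genes fell in 5 of 30 cases and rose in 2 in the third comparison and fell in 14 of 30 in the fourth comparison of the authors' deposited table (adjusted p 0.0449 and 0.000119, camera), and the first of these calls was lost with a preset correlation of 0.05 (adjusted p 0.145) and among genes of at least 2 CPM (adjusted p 0.339). The ribosomal medians stood at the percentiles 81.0 and 21.6 of random lists matched on base mean, so they were not unusually low for genes of like level. These medians, -0.18 and -0.46, were close to those of the first and the second comparison (-0.20 and -0.45), which have the same reference sets and the other numerator set. Of 3 metallothioneins with a test, 2 fell in each of these comparisons of the authors' deposited table, too few members for a list test. In the first comparison the added lists of cytosolic chaperones, ribosomal proteins and proteasome subunits were lower, with medians of -0.35, -0.20 and -0.15 in the authors' deposited table (adjusted p 2.34e-05, 0.000239 and 0.00702, camera). Targets of p53 and autophagy genes were higher there, with medians of 0.27 and 0.27 in the authors' deposited table (adjusted p 0.000320 and 0.00567, camera), and no member of these lists was called. The proteasome call was lost with a preset correlation of 0.05 (adjusted p 0.0561), and its median stood at the percentile 8.94 of matched lists. In the second comparison proteasome subunits, ribosomal proteins and cytosolic chaperones were lower, with medians of -0.51, -0.45 and -0.39 in the authors' deposited table (adjusted p 7.63e-10, 2.40e-08 and 0.00906, camera), and 1 proteasome gene was called. The chaperone call was lost with a preset correlation of 0.05 (adjusted p 0.0505).

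A rise of chaperone genes with HSPA6 at its head suggests a disturbance of protein folding or disposal, and a hypothesis from it is that proteasome genes rise too, as they do after proteasome inhibition. They did not. In the authors' deposited table, 14 of 31 proteasome subunits fell and none rose in the third comparison, at a median of -0.38, and 27 of 31 fell in the fourth, at a median of -0.76. The list was called lower in both (adjusted p 0.000238 and 4.08e-10, camera), and the calls held under each alternative of the list test. Its medians stood at the percentiles 14.2 and 0.15 of matched random lists, so by that measure the fall in the third comparison was not unusual for genes of like level. Proteasome subunits were lower in the second comparison too, at a median of -0.51 in the authors' deposited table. That comparison shares the reference set of the fourth, and its median of cytosolic chaperones was -0.39. Part of the fall in the fourth comparison may thus go with the reference set. The values argue against a compensatory rise at the time of sampling. Which agent the numerator set received, if any, stays open, and no explanation from the groups of the study was tested because no library could be tied to a group.

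The table departs from the described mouse libraries in organism, number of libraries and layout. A candidate explanation is that it comes from libraries other than the 10 described. The values of single reads gave 4 as the smallest number of libraries per comparison that accounts for all low counts, where groups of 2 and 3 would give 5, and comparisons of separate viruses would share no set. Another library of low depth would escape this count, but side means of matched sets agreed to an SD of at most 0.0019 with 2 libraries a side and of at least 0.038 with 2 and 3. The labels mention repeated sequencing, which could yield other numbers of columns, but not sets shared between the arms. Mouse fat reads counted on a human annotation are argued against, since the highest of ADIPOQ, CFD, LEP and PLIN1 in the first comparison of the authors' deposited table was 0.0542 CPM. This holds only if mouse reads of these genes would align to human sequence, which was not tested.

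Far fewer genes were called in the first and the second comparison than in the others. Numerator libraries of the first comparison differed 1.91-fold in size factor. In genes of at least 200 CPM the standard error was at the median 18.7 and 18.6 times the error from counting reads alone in the first and the second comparison. That counting error had medians of 0.0176 and 0.0186, against 0.0209 and 0.0217 in the third and the fourth. For these genes the values argue against read counting as the source of the larger standard errors. Other effects of the unequal depth were not tested. Lower depth is argued against, in a test chosen with the depths known: the shallowest library of the first and the second comparison had at least 1.29 times the reads of the shallowest of the third and the fourth, as derived from the authors' deposited table. The lowest median standard error of the first and the second comparison exceeded the highest of the third and the fourth by 0.124 in the authors' deposited table, while comparisons with the same numerator set differed by at most 0.0204. This is consistent with a larger spread between the libraries of the first numerator set. Fold changes were smaller as well. Across 9552 genes the SD of log2 numerator over reference means was 0.345 and 0.486 in the first and the second and 0.669 and 0.773 in the third and the fourth comparison, as derived from the authors' deposited table. The higher of the former was 0.726 of the lower of the latter. How much each contributes to the low counts of called genes stays open.

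Weakly expressed genes lay higher in the third and the fourth comparison. A single wrong scaling factor would move all classes alike, yet the median of genes at 0.1 to 0.5 CPM exceeded that of genes over 50 CPM by at least 1.32 on the log2 scale in the authors' deposited table. Deeper sequencing of the numerator set is argued against as well, since its mean size factor was at most 0.962 of that of the reference set. Residual genomic DNA or unspliced RNA in the numerator libraries could also raise such genes and was not tested, so the shift stays open.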
